A study of Rattus norvegicus with 18 samples.

How the data were processed

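RNA from cultured nucleus pulposus cells of Sprague Dawley rats aged 8 weeks was sequenced in 18 libraries, 3 for each of 6 groups. The groups were PDS, Phen-DC3 and Braco-19, each given for 24 hours, and 3 control groups. The titles of 2 control groups name PDS and Phen-DC3. The remaining control group names no compound and was paired with Braco-19 by elimination. The doses are not in the labels. The study's description calls the 3 libraries of a group biological repeats, and the labels do not say whether they came from separate cultures or animals. The p-values therefore measure differences against the spread between libraries of the same group, pooled over the 6 groups. That spread was not equal. Squared differences between 2 replicates, per gene and relative to counting error, were 13.6 to 36.4 in Phen-DC3 controls and 6.84 to 17.0 with Phen-DC3. In the other groups they were 4.27 to 13.1. The pooled spread can therefore be too small for Phen-DC3 and too large for the other compounds.

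The deposited table holds raw counts per gene, whole numbers that were not normalised, for 33898 genes, with gene identifiers, symbols, positions and the length of each gene model. The submitters' processing notes name CASAVA, HISAT2 (no version given) and featureCounts 1.5.0-p3. The genome build, the annotation release and the strandedness are not given in the sources used here. Library totals ran from 15715121 to 18369443 counts. Reads without molecular identifiers are not independent molecules, so counting error is a lower limit of the error. Reads that near-identical gene copies share could have been split between them, and values of Tpi1, Hmgb1, Rpl38 and Nhp2 are uncertain for this reason.

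Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr by group, which left 14184 genes, of which 702 were gene models without an Ensembl identifier. TMM factors scaled the libraries. A single quasi-likelihood model with robust dispersions and 1 mean per group was fitted to the 18 libraries, with 12 residual degrees of freedom. Each compound was compared with its own controls by the quasi-likelihood F-test, which is two-sided. The differences between the effects of pairs of compounds were tested as interaction contrasts in the same model, and the 3 control groups were compared with each other. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistics. Counts scaled to library size (CPM) are given as mean and SD over 3 libraries, on TMM-scaled library sizes.

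Before the data were examined, 41 gene lists were fixed, covering disc matrix, matrix enzymes, inflammation, DNA damage, the cell cycle, stress responses, metabolism, G-quadruplex biology and markers of other cell types. Of 1095 symbols in the lists, 1051 matched by symbol and 9 by an older name. Lists with at least 3 tested genes were tested with camera in limma at its preset correlation of 0.01, against the other genes, and the p-values were adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were run beside it. List members were also counted after adjustment over the list alone.

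The genes to be named were also set by a rule fixed before the data were examined. Per compound it takes the 8 higher and 8 lower genes with the largest changes among genes past the threshold, with a mean log2 CPM of at least 3, a gene symbol, and all 3 treated libraries on 1 side of all 3 controls. It adds up to 4 members of each list with the smallest p, and a set of disc and stress genes chosen in advance (such as Acan, Sox9, Il6 and Cdkn1a), of which Il1b had too few counts to be tested. For a difference between compounds it takes the 5 largest in each direction. Genes named outside this rule are stated as such, except markers of cell types that are given only for their level. The text names part of the genes that the rule takes, and a further gene for Phen-DC3 is not reported here.

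The calling was tested on simulated data built on the dispersions of these libraries, with 100 genes changed at each size. With 14057 genes in step for PDS, 48 were recovered at a log2 change of 0.5 and 75 at 1, with 3 false calls. With 14032 genes for Phen-DC3, 39 and 83 were recovered, with 5 false calls. With 14051 genes for Braco-19, 49 and 86 were recovered, with 8 false calls. These draws treat genes as independent and hold no trend between libraries, so they do not measure false calls from such a trend. With a length trend put on the treated libraries and no gene changed, 159, 204 and 182 genes were called, in the same order. Correction for the trend left 1, 0 and 0. The Spearman correlation with length was -0.573 there for Phen-DC3, and -0.443 in the data.

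Alternatives set before the data were examined were other normalisations (RLE, upper quartile), no count filter or a CPM filter, a block for the replicate number, a minimum absolute log2 change of 1, DESeq2 1.42.0, fits of the 6 libraries of a comparison alone, pooled controls, and leaving out each library in turn. Pooling adds the differences between control groups to the spread and to the contrast, so it does not test a compound alone. A correction of each library for its trend with gene length (lowess, span 0.3) and fits without the Braco-19 experiment were added after seeing the data. So were upper-quartile scaling and no count filter for the comparisons of controls, and RLE scaling, fits of 6 libraries and leaving out libraries for the lists. Pooling the 6 controls of the PDS and Phen-DC3 experiments, and leaving out libraries for differences and control comparisons, were also added then. Tests for G-quadruplex motifs near genes were not run, because no genome sequence was used here. Other splits of the libraries were counted, 10 for each pair of groups and 40 drawn for each difference between compounds. For PDS against each other compound, the 20 splits of the second experiment with PDS as labelled, and the chance counts of overlaps by DESeq2, were added after seeing the data. Correlations of fold changes and exact tests of shared genes are across genes, which are not independent replicates.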

Results

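Gene expression was measured by RNA sequencing in cultured rat nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc. Cells were exposed for 24 hours to PDS, Phen-DC3 or Braco-19, small molecules that bind and stabilise G-quadruplexes, which are folded structures of guanine-rich DNA and RNA. The 18 libraries formed 6 groups of 3, with a control group for each compound. Library totals were 15715121 to 18369443 counts, and 14184 genes were tested. Gene positions are as the deposited table gives them, and the build is not given in the sources used here. Values after ± are standard errors for log2 fold changes, on the spread pooled over the 6 groups, and SD for CPM, with n = 3 libraries per group.

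The first question was which genes changed under PDS. Interferon-response and inflammatory genes were among the most strongly raised. Cxcl10, a chemokine induced by interferon, rose 3.91-fold, from 44.4 ± 12.3 to 174 ± 10.5 CPM (log2 1.97 ± 0.23, adjusted p = 0.00017). Plau, which encodes the urokinase plasminogen activator, rose by 1.85 ± 0.14 on the log2 scale (6.63 ± 0.20 to 23.9 ± 2.65 CPM, adjusted p = 6.7e-08). Usp18, a protease that removes ISG15, rose by 1.90 ± 0.18, and Nos2, the inducible nitric oxide synthase, by 1.70 ± 0.46 (adjusted p = 0.041). Scara5, a scavenger receptor for ferritin, had a log2 change of -1.24 ± 0.08 (138 ± 4.84 to 58.5 ± 2.45 CPM, adjusted p = 4.7e-09). Il1rn, the interleukin-1 receptor antagonist, had a log2 change of -1.26 ± 0.16, and Lgr5, a receptor for R-spondins, -1.11 ± 0.14. These genes are ENSRNOG00000022256 (Cxcl10, chromosome 14, 17210733 to 17212930), ENSRNOG00000010516 (Plau, chromosome 15, 3644769 to 3650819) and ENSRNOG00000014398 (Scara5, chromosome 15, 49069145 to 49177166).

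Cell division genes rose together under PDS. Of 33 tested mitosis genes, 30 rose, 0 fell and 3 were not called, and 32 rose when adjusted over the list alone (camera adjusted p = 2.1e-37, and adjusted p = 0.0031 with an estimated correlation). Prc1, a cytokinesis protein, rose by 0.57 ± 0.07, Nusap1, a spindle protein, by 0.77 ± 0.10, and Aurka, the mitotic kinase, by 0.58 ± 0.08. Without PDS replicate 3, 19 mitosis genes were called higher. Among 45 genes of DNA replication, 7 rose, 0 fell and 38 were not called (13 higher, adjusted over the list alone). Mcm4, a helicase subunit, rose by 0.39 ± 0.09 and Tyms, the thymidylate synthase, by 0.39 ± 0.09. Among 41 genes of homologous recombination, 7 rose, 0 fell and 34 were not called (13 higher, adjusted over the list alone), including Fanci at 0.46 ± 0.09 and Brca1 at 0.61 ± 0.15. The camera adjusted p of the replication list was 3.7e-05 and that of the recombination list 1.9e-05. With an estimated correlation these became adjusted p = 0.073 and adjusted p = 0.070. Replication genes called higher numbered 4, 3 and 1 without PDS replicates 1, 2 and 3 and 0 without PDS control replicate 2, and recombination genes 4 and 2 without PDS replicates 2 and 3 and 4 without PDS control replicate 2 or 3.

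Of 34 interferon-response genes, 20 rose, 0 fell and 14 were not called under PDS (26 higher and 1 lower, adjusted over the list alone). The camera adjusted p was 3.7e-23, and adjusted p = 0.00098 with an estimated correlation. Ifit3 rose by 1.80 ± 0.27, Oasl by 1.70 ± 0.19 and Gbp5, a guanylate-binding protein, by 1.24 ± 0.13. Of 38 NF-kB and inflammatory genes, 13 rose, 1 fell (Sod2, named after its values were seen) and 24 were not called (18 higher and 3 lower, adjusted over the list alone). For the list, camera gave adjusted p = 1.8e-09, and adjusted p = 0.0031 with an estimated correlation. Ccl2, a monocyte chemokine, rose by 0.65 ± 0.09 to 1891 ± 74.0 CPM, Lif by 0.88 ± 0.12 and Il6 by 1.11 ± 0.22 (3.77 ± 0.92 to 8.13 ± 0.38 CPM). Of 35 genes of hypoxia and glycolysis, 16 rose, 0 fell and 19 were not called (18 higher, adjusted over the list alone). Their camera adjusted p was 2.9e-15, and adjusted p = 0.00098 with an estimated correlation. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 0.89 ± 0.09, Bnip3, a mitophagy receptor, by 0.69 ± 0.08, and Epas1, which encodes HIF-2α, by 0.76 ± 0.10.

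Of 34 p53 targets, 8 rose, 1 fell (Xpc, named after its values were seen) and 25 were not called under PDS, the same counts when adjusted over the list alone. Camera gave an adjusted p of 0.012, and adjusted p = 0.047 with an estimated correlation. Cdkn1a, the inhibitor p21, rose by 0.34 ± 0.07 and Mdm2, the p53 ubiquitin ligase, by 0.58 ± 0.08. Of 19 genes with well-studied promoter quadruplexes, 4 rose, 0 fell and 15 were not called (5 higher, adjusted over the list alone). The camera adjusted p was 0.0083, and adjusted p = 0.047 with an estimated correlation. They were Ccnd1 at 0.63 ± 0.07, Vegfa at 0.55 ± 0.09, Pdgfa at 0.32 ± 0.08 and Birc5 at 0.30 ± 0.08. Myc, a member of that list, was not called (0.30 ± 0.10, adjusted p = 0.061). Of 28 NRF2 and oxidative stress genes, 5 fell, 0 rose and 23 were not called (1 higher and 5 lower, adjusted over the list alone). For the list, camera gave adjusted p = 0.0025, and adjusted p = 0.033 with an estimated correlation. Nqo1, a quinone reductase, had a log2 change of -0.56 ± 0.08 and Hmox1, the haem oxygenase, -0.43 ± 0.07. Of 25 cholesterol synthesis genes, 6 fell, 0 rose and 19 were not called (6 lower, adjusted over the list alone), including Lss at -0.44 ± 0.07 and Fdps at -0.46 ± 0.08. Camera gave an adjusted p of 0.0043, and adjusted p = 0.18 with an estimated correlation. Called p53 targets numbered 5 higher without PDS replicate 1, 2 or 3 or PDS control replicate 2, and promoter-quadruplex genes 2 without PDS replicate 3. Lower NRF2 genes numbered 3 without PDS replicate 1 or PDS control replicate 2 and 2 without PDS replicate 3 or PDS control replicate 3, and lower cholesterol genes 3 without PDS replicate 1 or 2 or PDS control replicate 2 or 3.

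Of 72 cytosolic ribosomal proteins, 1 fell (Rpl38), 0 rose and 71 were not called under PDS (0 called, adjusted over the list alone), and of 46 nuclear genes of oxidative phosphorylation, 2 fell (Ndufb9 and Ndufv1), 0 rose and 44 were not called (1 lower, adjusted over the list alone). Their medians were -0.15 and -0.13, with camera adjusted p = 4.4e-05 and 4.8e-04, and adjusted p = 0.57 and 0.52 with an estimated correlation. Of 13 housekeeping genes, 4 rose (Tfrc, B2m, Pgk1 and Hprt1), 0 fell and 9 were not called (5 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.094 with an estimated correlation). By edgeR, 0 ribosomal proteins were called without PDS replicate 2 or 3 or PDS control replicate 1 or 2. Lower oxidative phosphorylation genes numbered 1 without PDS replicate 1, and 0 without PDS replicate 2 or 3 or PDS control replicate 2 or 3. Housekeeping genes called higher numbered 2 without PDS replicate 2 or PDS control replicate 3 and 1 without PDS control replicate 2, and the camera adjusted p of that list was 0.052 without PDS control replicate 1.

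Matrix genes moved both ways under PDS. Of 17 genes of cartilage-type matrix, 1 rose, 3 fell and 13 were not called (2 higher and 4 lower, adjusted over the list alone; camera adjusted p = 0.64). With any 1 library left out, 0 of these were called higher, and 1 was called lower without PDS replicate 1 or 2 or PDS control replicate 1. Col2a1, the collagen II chain, had a log2 change of -0.82 ± 0.16 (17.3 ± 1.08 to 9.80 ± 0.99 CPM), and Vcan, the proteoglycan versican, rose by 0.63 ± 0.18. Of 21 matrix-degrading enzymes, 3 rose, 3 fell and 15 were not called (6 higher and 3 lower, adjusted over the list alone; camera adjusted p = 0.51). Mmp3, stromelysin, rose by 0.34 ± 0.08 to 3350 ± 67.9 CPM, while the aggrecanase Adamts5 had a log2 change of -0.77 ± 0.09. Mmp13 was not called (0.74 ± 0.22, adjusted p = 0.057), nor were Sox9 (0.38 ± 0.14, adjusted p = 0.12) and Adamts4 (-0.10 ± 0.20, adjusted p = 0.80). Acan had 0.22 ± 0.17 CPM with PDS and 0.18 ± 0.11 CPM in controls, near the detection limit.

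In all, 1148 genes passed the edgeR test under PDS, 728 higher and 420 lower. The 3 PDS libraries lay on 1 side of the 3 controls for 1144 of them. That held for 33.4% of the tested genes, where chance gives 10%. Genes picked by a test tend to be separated, and genes move together, so this share is not a test of the calls. It was 28.1% for Braco-19 and 22.1% for Phen-DC3, where 882 of 1136 called genes were separated. The count of called PDS genes was 563 without PDS replicate 3, 673 without PDS replicate 2, 659 without PDS control replicate 2, 751 without PDS control replicate 3, 2053 in a fit of the 6 libraries alone and 102 against all 9 controls pooled, and upper-quartile scaling gave 575 higher and 527 lower. Of 75 called genes chosen under the rule, 50 stayed called under each gene-level alternative, and the other 25 (B2m, Birc5, Brca1, Ca12, Cdh2, Col11a1, Cyp51, Fmod, Gins3, Gsta1, Gstp1, Hprt1, Mcm4, Mmp3, Ndufb9, Ndufv1, Nos2, Pdgfa, Pgk1, Recql4, Rpl38, Sox5, Top2a, Tyms and Vcan) lost the call under at least 1. The gene-level alternatives do not include all 9 controls pooled or the minimum log2 change of 1, under which 120 genes were called.

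**Figure D1:**
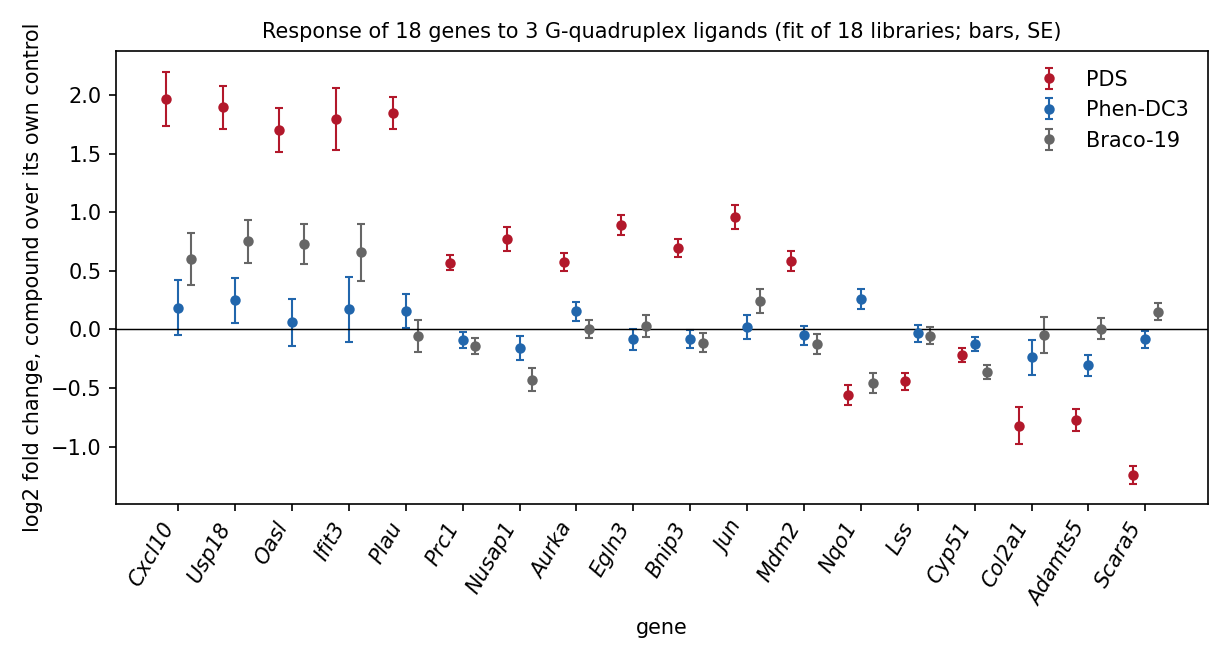
Log2 fold change against the compound's own controls (y axis) of 18 genes (x axis) for PDS, Phen-DC3 and Braco-19; points are estimates and bars standard errors, n = 3 libraries per group. Cxcl10 was at 1.97 with PDS, 0.18 with Phen-DC3 and 0.60 with Braco-19.

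The second question was which genes changed under Phen-DC3. Most called genes were lower, and the calls moved with a difference in the coverage of long genes between the libraries. Atrx, a chromatin remodeller that binds G-quadruplex-forming repeats, had a log2 change of -1.02 ± 0.21 (16.4 ± 3.75 to 8.05 ± 1.47 CPM, adjusted p = 0.016; ENSRNOG00000056703, chromosome X, 76820329 to 76979115). Smchd1, a protein of X inactivation, was at -0.94 ± 0.16. Crct1 rose by 0.90 ± 0.17 and the S100 protein S100a13 by 0.80 ± 0.22. Cdkn1a rose by 0.28 ± 0.07 (adjusted p = 0.026).

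Of 72 cytosolic ribosomal proteins, 18 rose, 0 fell and 54 were not called under Phen-DC3 (44 higher, adjusted over the list alone), such as Rplp0 at 0.34 ± 0.07 and Rps15 at 0.37 ± 0.08. Of 46 nuclear genes of oxidative phosphorylation, 17 rose, 0 fell and 29 were not called (25 higher, adjusted over the list alone), such as Ndufa2 at 0.44 ± 0.10. Of 32 proteasome genes, 9 rose, 0 fell and 23 were not called (16 higher, adjusted over the list alone), such as Psmb3 at 0.35 ± 0.07. Of 20 fibrillar matrix genes, 7 fell, 0 rose and 13 were not called (10 lower, adjusted over the list alone). Fn1, fibronectin, had a log2 change of -0.58 ± 0.11 and Fbn1, fibrillin, -0.56 ± 0.11. The camera adjusted p of these 4 lists was 9.4e-20, 2.7e-12, 4.2e-07 and 6.5e-06. With an estimated correlation none of the lists was called, with adjusted p = 0.47 for the first 3 and adjusted p = 0.54 for fibrillar matrix. Ribosomal proteins called higher numbered 39 without control replicate 3, 29 without Phen-DC3 replicate 3, 1 without control replicate 2 or Phen-DC3 replicate 2, and 0 by edgeR without replicate 1 of either group. Oxidative phosphorylation and proteasome genes called higher numbered 29 and 15 without control replicate 3, 27 and 14 without Phen-DC3 replicate 3, and 0 by edgeR without each of the other 4 libraries. Lower fibrillar matrix genes numbered 1 without Phen-DC3 replicate 2 and 0 by edgeR without replicate 1 of either group. After the length correction, 0 genes of these 4 lists were called by edgeR, with medians of 0.17, 0.11, 0.10 and -0.03 against 0.34, 0.26, 0.18 and -0.24 before. Fn1 was then at -0.17 and Fbn1 at -0.09. Of 13 mitochondrially encoded mRNAs, 1 fell (Mt-nd5), 0 rose and 12 were not called (1 lower, adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.0034, and adjusted p = 0.59 with an estimated correlation). Without control replicate 2 the camera adjusted p was 0.073. Lower genes numbered 8 without control replicate 3, 2 without Phen-DC3 replicate 3 and 0 by edgeR without each of the other 4 libraries.

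Of 33 G-quadruplex helicases and binding proteins, 6 fell, 0 rose and 27 were not called under Phen-DC3 (9 lower, adjusted over the list alone; camera adjusted p = 0.032, and adjusted p = 0.54 with an estimated correlation). Besides Atrx they included the topoisomerases Top2a at -0.47 ± 0.12 and Top2b at -0.50 ± 0.14, and the transcription factor Sp1 at -0.34 ± 0.08. Of 33 mitosis genes, 1 rose (Cdk1, 0.32 ± 0.07), 5 fell and 27 were not called (2 higher and 14 lower, adjusted over the list alone). The camera adjusted p was 0.048, and adjusted p = 0.65 with an estimated correlation. Mki67, a proliferation marker, had a log2 change of -0.85 ± 0.18. Of 17 cartilage-type matrix genes, 4 fell, 0 rose and 13 were not called (4 lower, adjusted over the list alone; camera adjusted p = 0.032, and adjusted p = 0.54 with an estimated correlation), including Col11a1 at -0.41 ± 0.09 and Vcan at -0.79 ± 0.18. Adamts5 had a log2 change of -0.31 ± 0.09. Col2a1 (-0.24 ± 0.15), Mmp3 (0.01 ± 0.08), Il6 (-0.16 ± 0.22) and Myc (0.01 ± 0.10) were not called. Of 34 interferon-response genes, 1 rose, 1 fell and 32 were not called (1 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.996).

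After the length correction, 0 helicase, mitosis and cartilage-type genes were called by edgeR. Top2a was then at -0.22, Top2b at -0.24, Mki67 at -0.39, Col11a1 at -0.03, Vcan at -0.26, Adamts5 at -0.23 and Atrx at -0.48. These counts also moved with single libraries. Lower helicase and binding-protein genes numbered 10 and 11, and lower mitosis genes 13 and 13, without replicate 3 of the control and of Phen-DC3, and both were 0 by edgeR without each of the other 4 libraries. Higher mitosis genes numbered 2 without either replicate 3 and 0 by edgeR without each of the others. Lower cartilage-type genes numbered 1 without control replicate 2 and 0 by edgeR without control replicate 1 or Phen-DC3 replicate 1 or 2. Interferon genes numbered 2 higher and 3 lower without control replicate 3, 1 and 4 without Phen-DC3 replicate 3, 0 and 1 without control replicate 2, and 0 of either by edgeR without the other 3 libraries. For the helicase list camera gave adjusted p = 0.12 without control replicate 2. For mitosis it gave 0.12, 0.16 and 0.26 without control replicates 2 and 1 and Phen-DC3 replicate 2. For cartilage-type matrix it gave 0.064, 0.0504 and 0.073 without Phen-DC3 replicates 1 and 2 and control replicate 2.

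In all, 1136 genes passed the edgeR test under Phen-DC3, 311 higher and 825 lower. Genes longer than 5000 bp took 9.98 ± 0.74% of counts in Phen-DC3 controls and 7.99 ± 0.52% in treated libraries, and the log2 fold change had a Spearman correlation of -0.443 with gene length across genes. After correction of each library for its length trend, 47 genes were called, 22 higher and 25 lower, 32 of them among the 1136, and Sp1 had a log2 change of 0.04. The count was 3 without control replicate 1, 129 without control replicate 2, 3315 without control replicate 3, 22 without Phen-DC3 replicate 2 and 2653 without Phen-DC3 replicate 3. By edgeR it was 0 without Phen-DC3 replicate 1 and 0 against all 9 controls pooled, with 2402 and 2625 genes at an unadjusted p under 0.05, 1 in a fit of the 6 libraries alone and 2106 with DESeq2 (836 higher and 1270 lower), and exchanging the 2 libraries labelled replicate 3 of Phen-DC3 and of its control gave 2607. Of the 45 called genes chosen under the rule, 0 stayed called under each gene-level alternative.

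**Figure D2:**
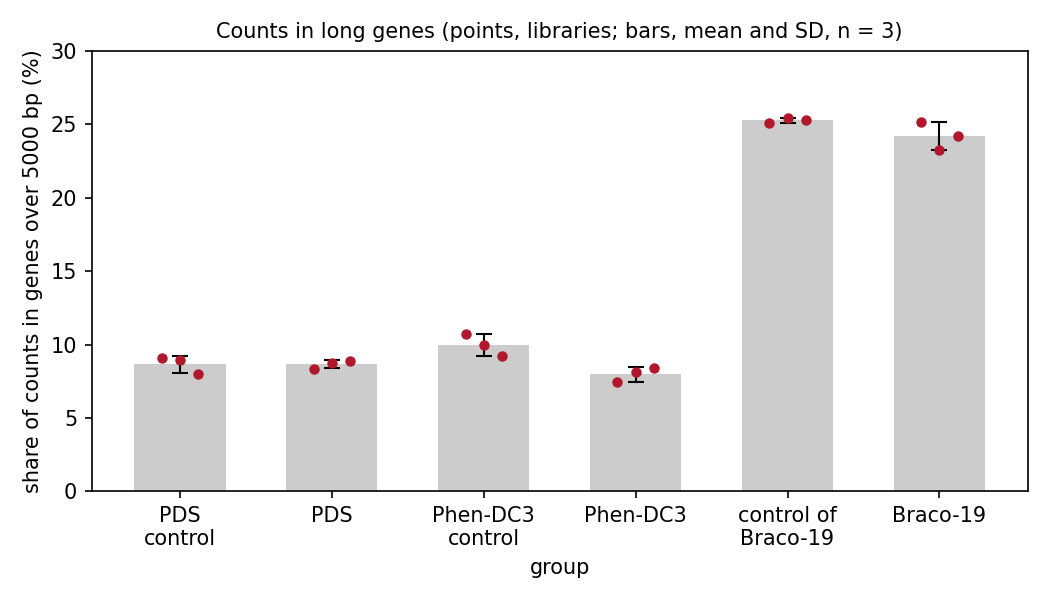
Share of counts (%, y axis) in genes longer than 5000 bp for each group (x axis); points are libraries, bars the mean and SD of 3 libraries. The share was 7.99% with Phen-DC3 and 9.98% in its controls, and 25.3% in the controls of Braco-19.

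The third question was which genes changed under Braco-19. Few genes passed the test, and interferon-related genes were among them. Apol9a, an apolipoprotein L family member, rose 2.22-fold, from 10.2 ± 2.09 to 22.6 ± 2.49 CPM (log2 1.15 ± 0.15, adjusted p = 0.0026; ENSRNOG00000023410, chromosome 7, 118927008 to 118933812). Per1, a circadian clock gene, rose by 0.70 ± 0.11 and Gbp2, a guanylate-binding protein, by 0.56 ± 0.09. The chemokine Ccl20 had a log2 change of -0.67 ± 0.11, Plat, the tissue plasminogen activator, -0.54 ± 0.09, and the quinone reductase Nqo1 -0.46 ± 0.08. The rise of Tpi1 (1.12 ± 0.21) and the fall of Hmgb1 (-0.75 ± 0.14) are uncertain, since both have near-identical copies.

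Of 34 interferon-response genes, 3 rose, 0 fell and 31 were not called under Braco-19 (19 higher, adjusted over the list alone). For the list, camera gave adjusted p = 5.9e-14, and adjusted p = 0.018 with an estimated correlation. The 3 were Gbp2, Irf7 at 0.54 ± 0.11 and Stat2 at 0.40 ± 0.08, and their number was 8 without Braco-19 replicate 1, 1 without control replicate 2 or 3, and 0 without control replicate 1 or Braco-19 replicate 2 or 3. Of 25 cholesterol synthesis genes, 2 fell, 0 rose and 23 were not called (10 lower, adjusted over the list alone). They were Cyp51 at -0.36 ± 0.06 and Sc5d at -0.45 ± 0.08 (camera adjusted p = 8.5e-08, and adjusted p = 0.048 with an estimated correlation), and 0 were called without control replicate 1 or 3 or Braco-19 replicate 3 and 1 without control replicate 2 or Braco-19 replicate 2. Of 28 NRF2 genes, 2 fell (Nqo1 and Gclc), 0 rose and 26 were not called (1 higher and 4 lower, adjusted over the list alone; camera adjusted p = 0.14), and 0 fell by edgeR without Braco-19 replicate 2 or 3 or control replicate 1 or 3. Of 72 ribosomal proteins, 0 were called over all genes and 30 rose when adjusted over the list alone (camera adjusted p = 1.4e-13, and adjusted p = 0.31 with an estimated correlation). Of 46 nuclear genes of oxidative phosphorylation, 0 were called and 13 rose when adjusted over the list alone (camera adjusted p = 4.8e-08, and adjusted p = 0.31 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, 0 were called and 1 fell when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 5.1e-05, and adjusted p = 0.38 with an estimated correlation). Mitochondrial genes took 2.28 ± 0.15% of counts with Braco-19 and 2.96 ± 0.30% in its controls, lower in each treated library than in each control. Without Braco-19 replicate 1, 3 ribosomal proteins and 2 oxidative phosphorylation genes rose and 1 mitosis gene fell. Of 33 mitosis genes, 0 were called and 4 fell when adjusted over the list alone (camera adjusted p = 2.8e-05, and adjusted p = 0.31 with an estimated correlation). Col2a1 (-0.05 ± 0.15), Mmp3 (-0.25 ± 0.08), Mmp13 (-0.53 ± 0.22), Adamts5 (0.01 ± 0.09), Cdkn1a (0.21 ± 0.07) and Mdm2 (-0.13 ± 0.08) were not called.

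In all, 39 genes passed the edgeR test under Braco-19, 24 higher and 15 lower, and 2660 had an unadjusted p under 0.05. The log2 fold change had a Spearman correlation of -0.225 with gene length across genes. The count was 3 without control replicate 1, 20 without control replicate 2, 6 without control replicate 3, 153 without Braco-19 replicate 1, 4 without replicate 2 and 1 without replicate 3. It was 359 with DESeq2, 781 in a fit of the 6 libraries alone and 0 by edgeR against all 9 controls pooled, with 4496 genes at an unadjusted p under 0.05. Of 22 called genes chosen under the rule, Apol9a stayed called under each gene-level alternative. Pooling of all 9 controls, which left 0 genes called by edgeR, mixes control groups that differ from each other and is not among these alternatives.

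The compounds were then compared with each other through their effects against their own controls. Doses are not in the labels and cannot be taken as matched. The control groups differed too. Between PDS and Braco-19 controls 10398 genes were called, between Phen-DC3 and Braco-19 controls 9860, and between PDS and Phen-DC3 controls 864. A difference between compounds cannot be told apart here from a difference in how these cultures respond. The PDS effect exceeded the Phen-DC3 effect for Nos2 by 2.99 ± 0.66 (95% interval 1.56 to 4.42), for Cxcl10 by 1.78 ± 0.33 (1.07 to 2.50), for Plau by 1.69 ± 0.20 (1.26 to 2.12) and for Mki67 by 1.65 ± 0.25 (1.10 to 2.20). It was below it for Ramp3, a receptor activity-modifying protein, by a difference of -1.37 ± 0.17 (-1.74 to -1.01), and for S100a6 by -1.35 ± 0.35 (-2.12 to -0.59). Of 33 mitosis genes, 25 differed, with a higher effect of PDS, and 8 were not called (28 higher, adjusted over the list alone). Of 34 interferon-response genes, 20 differed with a higher and 2 with a lower effect of PDS, and 12 were not called (24 higher and 3 lower, adjusted over the list alone). Camera gave adjusted p = 5.2e-20 for mitosis and 6.1e-09 for interferon response, and adjusted p = 0.056 with an estimated correlation for both. Of 72 ribosomal proteins, 37 differed with a lower effect of PDS and 35 were not called (50 lower, adjusted over the list alone; camera adjusted p = 4.0e-16, and adjusted p = 0.25 with an estimated correlation), and 14 differed after the length correction. In all 2862 genes differed, 1761 with a higher and 1101 with a lower effect of PDS. The count was 3942 with the 2 libraries labelled replicate 3 of Phen-DC3 and of its control exchanged, 1888 after the length correction, 1447 without Phen-DC3 replicate 1, 1778 without Phen-DC3 replicate 2, 1636 and 1839 without Phen-DC3 control replicates 1 and 2, 1511 without PDS replicate 3 and 1843 without PDS control replicate 2.

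The PDS effect exceeded the Braco-19 effect for Susd5 by 1.95 ± 0.18 (95% interval 1.56 to 2.35), for Plau by 1.90 ± 0.19 (1.49 to 2.32), for Ptgs2, the inducible cyclooxygenase, by 1.67 ± 0.25 (1.11 to 2.22), and for Chsy3, a chondroitin synthase, by 1.62 ± 0.13 (1.34 to 1.90). It was below it for Tril by a difference of -1.73 ± 0.19 (-2.14 to -1.33) and for Gas1 by -1.53 ± 0.28 (-2.14 to -0.93). Of 33 mitosis genes, 26 differed with a higher effect of PDS and 7 were not called (29 higher, adjusted over the list alone; camera adjusted p = 8.0e-27, and adjusted p = 0.019 with an estimated correlation). Of 38 NF-kB and inflammatory genes, 13 differed with a higher and 1 with a lower effect of PDS, and 24 were not called (17 higher and 1 lower, adjusted over the list alone; camera adjusted p = 5.0e-07, and adjusted p = 0.019 with an estimated correlation). Of 34 interferon-response genes, 7 differed with a higher and 2 with a lower effect of PDS (7 and 2, adjusted over the list alone; camera adjusted p = 0.054). For Nqo1, which fell with both compounds, the difference was -0.10 (95% interval -0.36 to 0.16), and for Gbp2, which rose with both, -0.06 (-0.32 to 0.21). In all 1990 genes differed, 1033 with a higher and 957 with a lower effect of PDS, and upper-quartile scaling gave 873 and 1174. The count was 896 without PDS replicate 3, 1264 without PDS replicate 2, 1123 without PDS control replicate 2, 1147 and 1297 without control replicates 1 and 3, and 975 and 1065 without Braco-19 replicates 2 and 3.

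Phen-DC3 and Braco-19 differed for 7 genes. The Phen-DC3 effect was higher for Nqo1 by 0.72 ± 0.12 (95% interval 0.46 to 0.97) and for Ier3, an immediate early gene, by 0.62 ± 0.11 (0.38 to 0.86). It was lower for Ifih1, the RNA sensor MDA5, by a difference of -1.27 ± 0.21 (-1.73 to -0.81), and for Pappa1, Per1, Ahnak and Anpep by -1.18, -0.87, -0.77 and -0.63. Of 34 interferon-response genes, 1 differed, with a lower effect of Phen-DC3, and 33 were not called (9 lower, adjusted over the list alone), with a median difference of -0.48 (camera adjusted p = 7.7e-11, and adjusted p = 0.045 with an estimated correlation). At an unadjusted p under 0.05, 1344 genes differed. The edgeR count was 0 after the length correction, with 1023 at an unadjusted p under 0.05, 4 with RLE scaling and 53 with DESeq2. It was 15 and 11 without replicate 3 of the Phen-DC3 control and of Phen-DC3, and 4, 3, 1 and 1 without Braco-19 replicate 3, control replicate 2, Phen-DC3 control replicate 1 and Braco-19 replicate 1. By edgeR it was 0 without Phen-DC3 control replicate 2, Phen-DC3 replicates 1 or 2, control replicates 1 or 3, or Braco-19 replicate 2, with 982 to 1319 at an unadjusted p under 0.05.

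Genes shared by the calls of 2 compounds were counted against chance, and the comparisons share no control libraries. The exact tests treat genes as independent, which they are not, so their p-values can be too small. PDS and Braco-19 shared 6 higher genes (Apol9a, Arhgap22, Ccl5, Cox4i2, Gbp2 and Irf7, where chance gives 1.23; two-sided Fisher's exact test, p = 0.0011) and 3 lower genes (Cyp51, Nqo1 and Scd, where chance gives 0.444; exact p = 0.0090). In opposite directions, 4 genes (Amd1, Chsy3, Plat and Stil) were higher with PDS and lower with Braco-19, where chance gives 0.770 (exact p = 0.0060). Another 5 (Angptl4, Gas6, Irf2bpl, Klf15 and Ptx3) were lower with PDS and higher with Braco-19, where chance gives 0.711 (exact p = 5.9e-04). PDS and Phen-DC3 shared 10 higher genes, including Cdk1 and Cdkn1a, where chance gives 15.96, and 19 lower genes, including Adamts1, Adamts5 and Col11a1, where chance gives 24.4. A further 70 genes, including Mki67 and Epas1, were higher with PDS and lower with Phen-DC3, where chance gives 42.3 (exact p = 2.9e-05), and 14 were lower with PDS and higher with Phen-DC3, where chance gives 9.21 (exact p = 0.12). Phen-DC3 and Braco-19 shared 1 higher gene (Mgmt) and 3 lower genes (Cyp1b1, Scd and Stil), where chance gives 0.526 and 0.873. Log2 fold changes across genes had a Spearman correlation of -0.325 between PDS and Phen-DC3, -0.382 between PDS and Braco-19 and 0.452 between Phen-DC3 and Braco-19 (Pearson -0.192, -0.202 and 0.276). The fold changes also followed gene length, with Spearman correlations of 0.174 for PDS, -0.443 for Phen-DC3 and -0.225 for Braco-19. After the length correction the correlations between compounds were -0.288, -0.362 and 0.421, in the same order. Genes called higher with PDS and lower with Phen-DC3 then numbered 2, where chance gives 1.20, as 47 genes were called for Phen-DC3. For PDS and Braco-19, 6 were then higher with PDS and lower with Braco-19, and 6 the reverse, where chance gives 0.914 and 0.990. The excess of shared genes for PDS and Braco-19 depended on the tool. With DESeq2 they shared 14 higher and 6 lower genes, where chance gives 17.2 and 8.09 (exact p = 0.52 and 0.58). By DESeq2, 57 were higher with PDS and lower with Braco-19 and 47 the reverse, where chance gives 11.6 and 11.9 (exact p = 5.2e-26 and 1.4e-16). PDS and Phen-DC3 then shared 29 higher and 37 lower genes, where chance gives 62 and 65.2, with 156 higher and lower and 71 lower and higher, where chance gives 94.2 and 42.9. Phen-DC3 and Braco-19 then shared 70 higher and 31 lower genes, where chance gives 20.1 and 19.8 (exact p = 6.3e-22 and 0.0098). Genes outside the naming rule were picked here after their values were seen.

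The 3 control groups were compared to measure how far the cultures differed without compound. Fn1, fibronectin, took 7.75 ± 0.04% of counts in the controls of Braco-19 and 0.88 ± 0.15% in those of PDS. Mki67 was at 611 ± 32.2 CPM in the controls of Braco-19 and at 25.5 ± 5.22 CPM in those of PDS, 24.0-fold lower (log2 -4.58 ± 0.19). Of 33 mitosis genes, 30 were lower, 1 was higher and 2 were not called in PDS controls than in Braco-19 controls, the same counts when adjusted over the list alone (camera adjusted p = 3.9e-16, and adjusted p = 0.076 with an estimated correlation). Of 35 hypoxia and glycolysis genes, 25 were higher, 7 were lower and 3 were not called, again the same when adjusted over the list alone (camera adjusted p = 8.5e-09, and adjusted p = 0.023 with an estimated correlation). Genes longer than 5000 bp took 25.3 ± 0.18% of counts in Braco-19 controls and 8.66 ± 0.59% in PDS controls. The log2 fold change between these controls had a Spearman correlation of -0.496 with gene length across genes. The Mki67 change and the list results are given without the length correction, so part of them may follow gene length. Between PDS and Braco-19 controls 10398 genes differed, 5044 higher and 5354 lower in PDS controls, but upper-quartile scaling, which moved the median gene by 0.11, gave 5601 and 4865, and the length correction 4999 and 4527. Between Phen-DC3 and Braco-19 controls 9860 differed, 4909 higher and 4951 lower in Phen-DC3 controls, but upper-quartile scaling, which also moved the median gene by 0.11, gave 5485 and 4388, the length correction 4716 and 4181, and no count filter 4973 and 4852. The experiment and the control group cannot be told apart here.

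Between PDS and Phen-DC3 controls 864 genes differed, 226 higher and 638 lower in PDS controls. Of 45 DNA replication genes, 17 were higher in PDS controls, 0 were lower and 28 were not called (21 higher and 2 lower, adjusted over the list alone; camera adjusted p = 3.0e-12, and adjusted p = 0.031 with an estimated correlation). The count of 864 was 468 after the length correction, 1599 with DESeq2, 9 and 261 without PDS control replicates 2 and 3, 37 and 2740 without Phen-DC3 control replicates 1 and 3, and 0 by edgeR without Phen-DC3 control replicate 2, with 2650 at an unadjusted p under 0.05.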

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

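The tests of leukocyte genes, of the 10 most abundant genes, of a length trend in the Phen-DC3 and interferon results and of interferon genes over the 3 compounds were chosen after the result was seen, as were the 20 splits with PDS as labelled, and the test of exchanged labels was set after 2607 genes had been seen for that split without the length correction.

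The effects of PDS and Phen-DC3 differed for 2862 genes, those of PDS and Braco-19 for 1990, and those of Phen-DC3 and Braco-19 for 7, each by an interaction test. Other splits of the libraries within each experiment, 40 in all with the real one, gave at most 1169 genes for PDS against Phen-DC3 and at most 216 for PDS against Braco-19. Among those drawn the real split alone (1 of 40) gave as many. Most of the drawn splits also broke the PDS labels, which removes the PDS effect itself. They therefore cannot decide whether the effects of 2 compounds differ by chance. The 20 splits of the second experiment with PDS as labelled are too few for a share under 0.05, and the highest other count there was 587 for PDS against Braco-19. For PDS against Phen-DC3, the split that exchanges the 2 libraries labelled replicate 3 of Phen-DC3 and of its control was not among the 40 drawn and gave 3942 genes, so 2 of those 20 splits gave as many. Chance was thus not excluded for either difference from PDS. In all these differences, the compound also cannot be told apart from the cultures it was given to. For Phen-DC3 against Braco-19, 2 of 40 splits gave at least 7 genes and the highest other split gave 330, so chance cannot be excluded.

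The genes called under Phen-DC3 were mostly lower and fell on long genes. A length trend between the libraries may account for much of this, since after its removal 32 of the 1136 genes were still called. Their median absolute log2 change went from 0.439 to 0.241 and their median standard error from 0.113 to 0.0946, so the calls ended because the changes shrank, not because the spread grew. A mix-up of the 2 libraries labelled replicate 3 of Phen-DC3 and of its control is also a candidate explanation, because exchanging them with the length trend removed gave 2239 genes against 47 as labelled. That split was picked because it had given the most genes before the correction. It therefore cannot decide between a mix-up and another structure of the samples. An axis on which replicates of a group vary was tested with the PDS experiment, from PDS-treated and control libraries together. It had r = -0.151 across genes with the Phen-DC3 change, which leaves it open, and a response to the compound also stays open.

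The controls of the Braco-19 experiment stood apart from the other controls. A length trend as the whole cause is argued against by the counts after its removal. Of the 10398 genes that differed from PDS controls, 8095 were then called, counted in either direction, and 9012 of the 10398 kept their direction. The median absolute log2 change of the 10398 genes was 0.677 against 1.00 before. A few genes taking most of the counts are argued against too, since the 10 most abundant genes took at most 13.9% of counts in these libraries. No biological explanation was tested, because the experiment and the control group cannot be separated in this design.

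Interferon-response genes were higher in PDS libraries. Leukocytes in the cultures are argued against, since 6 leukocyte genes summed to at most 0.415 CPM in a PDS library. A length trend is argued against as well, since the 20 interferon genes called higher were the same genes before and after its removal, with a median log2 change of 1.27 before and 1.24 after and a median standard error of 0.198 and 0.195. An interferon response to quadruplex ligands as a class could not be decided. The list was not called higher with Phen-DC3 (camera adjusted p = 0.996), where its median log2 change was 0.0810, the lowest over the compounds. However, the Phen-DC3 libraries carry the doubts above, and the doses are not in the labels. A response to PDS itself remains a hypothesis.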

How the results depend on the processing

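The gene-length correction, upper-quartile scaling and no count filter for the control comparisons, RLE scaling and fits of 6 libraries for the lists, the fits without the Braco-19 experiment and those with the 6 controls of the other experiments pooled were chosen after seeing the data, as was leaving out libraries for differences, control comparisons and lists, and as was the reading of Phen-DC3 without its control replicate 1 as a test of that library. Where a count moved by over 1.5 times, the cause was not tested, with the following exceptions. A minimum change removes calls by construction. Pooling control groups adds the differences between them to the spread by construction. The length correction shrank the Phen-DC3 changes, as given above. Scaling by RLE or upper quartile and other count filters kept each count within 1.5 times, except that RLE gave 4 genes for Phen-DC3 against Braco-19. With a block for the replicate number, which did not pair the libraries (correlations of same-number deviations -0.251 to 0.0717), the counts were 587 for PDS, 1 for Phen-DC3, 2 for Braco-19, and for the differences PDS against Phen-DC3 1161, PDS against Braco-19 661 and Phen-DC3 against Braco-19 1. The length correction gave 47 for Phen-DC3, 1888 and 0 for PDS and Braco-19 against Phen-DC3, and 468 for PDS against Phen-DC3 controls, and Sp1 and Atm reversed to log2 changes of 0.039 and 0.0072 under it. At an absolute log2 change of at least 1 the counts were 120, 48 and 5 for the compounds and 446, 287 and 2 for the differences. DESeq2 gave 2106 for Phen-DC3, 359 for Braco-19, 53 for Phen-DC3 against Braco-19 and 1599 for PDS against Phen-DC3 controls. It left 3855 genes without an adjusted p for Phen-DC3 and 5775 for Braco-19. At an unadjusted p under 0.05 it had 4140 and 2707 genes, against 4096 and 2660 by edgeR, so the tools differed less before adjustment. The 6 libraries alone gave 2053, 1 and 781, and all 9 controls pooled gave 102, 0 and 0. For Phen-DC3 the 6 pooled controls and the 12 libraries without the Braco-19 experiment gave 0 each, with 1316 and 3721 genes at an unadjusted p under 0.05 in edgeR. Leaving out 1 library gave 563 to 867 for PDS, 0 to 3315 for Phen-DC3 (3 without control replicate 1), 1 to 153 for Braco-19, 1447 to 4218, 896 to 2353 and 0 to 15 for the differences, and 0 to 2740 for PDS against Phen-DC3 controls, while the comparisons with Braco-19 controls stayed within 9973 to 10094 and 9266 to 9702. Genes shared in the same direction by PDS and Phen-DC3 numbered 66 with DESeq2, 0 at a log2 change of 1 and 1 after the length correction, by PDS and Braco-19 20 and 1 for the first 2 settings, and by Phen-DC3 and Braco-19 101, 0 and 0. Lists past the threshold with an estimated correlation numbered 7 for PDS, 0 for Phen-DC3 and 2 for Braco-19, against 14, 9 and 10 with the preset, and for Phen-DC3 5 after the length correction and 4 to 9 with 1 library left out. With the depth of 15715121 to 18369443 counts, Il1b could not be tested, and Acan was near the detection limit in the PDS and Phen-DC3 experiments.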

Other observations

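The test of genomic span was chosen after the result was seen. The tests of other splits were planned.

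The cultures expressed some markers of the nucleus pulposus at low to moderate levels, with mean values in the controls of PDS, Phen-DC3 and Braco-19 of 78.1, 77.5 and 110.5 CPM for Pax1, 35.1, 39.3 and 40.1 for Foxf1, 37.2, 40.6 and 13.6 for Cd24, and 6.72, 7.01 and 14.9 for Sox9. Of 19 nucleus pulposus and notochord markers listed, 12 had enough counts to be tested. Low ones had means over the libraries of 0.99 CPM for Ca12, 0.67 for Foxa1, 0.12 for Foxa2, 0.02 for Gpc3 and 0.01 for Krt18. Acan was near the detection limit in the PDS and Phen-DC3 experiments. Tbxt, Shh, Noto and Krt19, markers of notochordal cells, had 0 counts in each library. Of markers of other cell types, Ptprc (leukocytes), C1qa (macrophages) and Cdh5 (endothelium) also had 0 counts in each library, while in the same order the broader markers Cd14 and Pdgfrb had means of 109.4, 101.8 and 33.8 CPM and of 116, 135 and 338 CPM, and the fibroblast collagen Col1a1 1357, 1439 and 4821 CPM. Other annulus and tendon fibroblast markers were also expressed, with 934, 813 and 556 CPM for Thy1, 237, 332 and 227 for Dcn, and 107, 85.0 and 47.1 for Scx. Others of that list were low, with means over the libraries of 0.70 CPM for Dpt and 0.08 for Cd34, and 0 counts for Tnmd. Of 12 listed hypertrophic chondrocyte and bone markers 4 were tested, among them Spp1 at 3559, 4283 and 6585 CPM in the same control groups. The share of cells of other types was not tested. Of 12 tested nucleus pulposus and notochord markers, 3 rose with PDS (Ca12, Cdh2 and Sox5), 0 fell and 9 were not called (4 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.51), and 1 rose without PDS replicate 1, 2 or 3 or PDS control replicate 2 or 3. None of these markers was called with Phen-DC3 or Braco-19, where 0 and 1 were called when adjusted over the list alone.

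Other lists were tested under PDS, with counts that moved when 1 library was left out. Of 25 immediate early genes, 6 rose, 0 fell and 19 were not called (8 higher and 1 lower, adjusted over the list alone), with Jun at 0.96 ± 0.10 and Fosl1 at 0.56 ± 0.07 (camera adjusted p = 7.4e-04, and adjusted p = 0.053 with an estimated correlation, which was 0.0497 without PDS replicate 3 and 0.0485 without PDS control replicate 2). Of 20 fibrillar matrix genes, 4 rose, 1 fell and 15 were not called (6 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.11), with the collagen-crosslinking enzyme Loxl2 at 0.75 ± 0.07. Of these, 2 rose without PDS replicate 1 or 3 or PDS control replicate 3, and 2 fell without PDS control replicate 3. Camera gave adjusted p = 0.041, 0.036 and 0.010 without PDS replicate 1, PDS control replicate 1 and PDS control replicate 2. Of 33 G-quadruplex helicases and binding proteins, 2 rose, 0 fell and 31 were not called (4 higher, adjusted over the list alone; camera adjusted p = 0.20). The 2 were Top2a and Recql4. Without PDS replicate 2 or 3, 1 rose, and 0 rose by edgeR without PDS replicate 1 or PDS control replicate 2 or 3.

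Genes with a long genomic span may respond to Phen-DC3. The partial Spearman correlation of the Phen-DC3 log2 change with span, given transcript length, was -0.167. It was -0.152 between PDS and Phen-DC3 controls, but both comparisons use the same 3 Phen-DC3 control libraries, so part of that agreement is built in. For Braco-19, whose comparison shares no library with that of Phen-DC3, it was -0.151, and for PDS it was 0.0989. A trend of this size was thus not particular to Phen-DC3, and the hypothesis stays open.

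Other splits of the 6 libraries of a comparison, 10 each with the real one, are too few for a share under 0.05. The real split gave 1148 genes for PDS and the highest other split 0. It gave 39 for Braco-19 and the highest other 0. For Phen-DC3 the real split gave 1136 and the highest other 2607, with 2 of 10 splits at or above the real one. For the controls of PDS and Phen-DC3 the values were 864 and 1, for PDS and Braco-19 controls 10398 and 1, and for Phen-DC3 and Braco-19 controls 9860 and 1.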
